A study of Mus musculus with 4 samples.

How the data were processed

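Primary fibroblasts from the ears of C57BL/6 mice were grown in DMEM with fetal calf serum. Per the labels, cells were held for 48 h with KN93, an inhibitor of calmodulin-dependent kinase II used to synchronize the cell cycle, and then transfected for 24 h. RNA was extracted with TRIzol from whole-cell lysates or from a pulldown with an antibody against fibrillarin (Abcam ab5821), and the pulldown RNA was depleted of ribosomal RNA before sequencing on the DNBseq platform. The labels disagree on the treatment: the sample characteristics name overexpression (AF357425-High) and inhibition (AF357425-Low) of AF357425, while the treatment protocol names gapmers, antisense oligonucleotides that recruit RNase H, against AF357425 or a scrambled control. The groups follow the sample titles, and which transfection stands behind each group is not given in the sources used here. Each of the 4 groups has 1 library, and whether the libraries of a state came from the same culture, or the states from the same mice, is not given in the sources used here.

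The authors deposited counts of fragments per gene, in a table for the whole-cell libraries and another for the pulldown libraries. Per the submitters' processing notes, reads were trimmed with cutadapt 2.4, aligned to GRCm38 with STAR 2.6.0c and counted with HTSeq 0.9.1, and StringTie 1.3.4 was also used. The gene annotation and the strand setting of the counting are not given in the sources used here, and the setting could differ between the kinds of library. The tables held whole numbers for 55536 Ensembl genes and, besides, the summary lines of HTSeq, which were left out of the gene values and used for the shares that follow. Of all fragments, 40170456 and 38565766 in the AF357425-High and AF357425-Low whole-cell libraries and 51695861 and 50955079 in the pulldowns, 55.0%, 56.2%, 50.0% and 54.6% were assigned to a gene. Not aligned were 6.99%, 6.47%, 13.4% and 12.5%, and not uniquely aligned were 11.3%, 11.2%, 18.3% and 17.8%. Genes with at least 1 read numbered 23811, 23506, 18993 and 20769. A count of 0 was limited at 3 reads, which is 0.136, 0.138, 0.116 and 0.108 CPM in the same order.

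Symbols were paired with 55450 gene IDs, and the class of the RNA and the position (GRCm38.p6) with 38690 IDs by symbol from RefSeq annotation; 109 symbols sat on several IDs. Whether a gene's span overlaps another gene was read from the RefSeq spans on either strand. Genes with a mean of at least 1 CPM over the libraries compared were measured. The states were compared within each kind of library after TMM scaling in edgeR 4.0.16 (R 4.3.3), with factors of 1.02 and 0.978 in whole-cell RNA and 0.903 and 1.11 in the pulldown. The pulldown was compared with whole-cell RNA of the same state by library totals, since mitochondrial ribosomal RNA filled most of the pulldown and TMM assumes that most genes do not differ. The change of the pulldown-to-whole-cell ratio between the states was the difference of the log2 ratios of the state comparisons, for genes with at least 10 reads in each library.

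Because each group has 1 library, no test between groups was run. Each ratio has a 95% interval from the counts: exact (Clopper-Pearson) for a pair of libraries and a normal approximation on the log scale for the change over 4 libraries. A gene was called higher or lower where the whole interval lay beyond 2-fold, and pulldown against whole-cell calls for single genes required this in both states. A gene with 0 reads in a library of the pair is given as at least as many fold as the floor of 3 reads allows. For each of 40 gene lists written before the files were seen, the median log2 ratio was set against 10000 random lists drawn in 20 expression bins. Its percentile describes these libraries and is no test between groups, and a list counts as apart below percentile 2.5 or above 97.5. Over 40 lists per comparison some fall outside by chance. Tables with 200 changed genes were simulated with counting error only (Poisson) and known library totals. They hold no variation between cultures or from PCR, so they check the computation and not false calls in the real libraries. In them, intervals held the true ratio for 95.1% to 95.7% of genes and no unchanged gene passed the line. Between 0 and 3 of 40 unchanged lists stood apart. At 4-fold, 92.4% to 97.3% of changed genes were recovered, and at 2.5-fold 55.6% to 71.1%.

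The lists were the Dlk1-Dio3 locus, C/D box snoRNAs, H/ACA box snoRNAs, Cajal body RNAs, C/D snoRNP proteins, H/ACA snoRNP proteins, snoRNA host genes, small nuclear and other structured RNAs, integrin subunits, integrin signalling, collagens, other extracellular matrix, matrix proteases and inhibitors, contractile and myofibroblast genes, TGF-beta and YAP targets, fibroblast markers, growth factors and receptors, chemokines and cytokines and interferon response. The remaining ones were p53 response, unfolded protein and integrated stress response, heat shock, immediate early genes, proliferation, replication-dependent histones, cytoplasmic ribosomal proteins, ribosome biogenesis, splicing factors, mitochondrially encoded genes, nuclear oxidative phosphorylation, cholesterol synthesis, RNase H and oligonucleotide binding, and markers of keratinocytes, endothelium, macrophages and leukocytes, smooth muscle and pericytes, skeletal muscle, chondrocytes, adipocytes, and Schwann cells and melanocytes. By a rule set before the files were seen, the named genes are AF357425 and the measured Dlk1-Dio3 genes, the 12 highest and 12 lowest genes of each comparison by the interval bound nearest 0 with at least 100 summed reads and a gene name that is not a clone or pseudogene name, and up to 4 members per list with the largest bound. Not every gene so chosen is printed.

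The alternatives were library totals, median-of-ratios, upper-quartile scaling and totals without the 20 most abundant genes (for the pulldown against whole-cell RNA, TMM and totals of protein-coding genes among them), lines at 1.5-fold and 4-fold, the 2-fold line without the interval, no filter, a mean of at least 5 CPM, at least 50 reads for the change of the ratio, and random lists of protein-coding genes. Protein-coding genes without an overlapping gene were added as an alternative after the data were seen. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9. Splicing and 2'-O-methylation cannot be read from counts per gene and are not analysed here.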

Results

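RNA was sequenced from primary fibroblasts grown from ear clippings of C57BL/6 mice, in 2 states of AF357425, a C/D box small nucleolar RNA (snoRNA) of the imprinted Dlk1-Dio3 locus and the mouse counterpart of human SNORD113-6. C/D box snoRNAs guide the methyltransferase fibrillarin to ribosomal and other RNAs, where it methylates the 2'-hydroxyl of the ribose. The labels name the states AF357425-High and AF357425-Low. For each state, a library of whole-cell RNA and a library of RNA from a fibrillarin pulldown were deposited, which makes 4 libraries with 1 in each group. No difference given here therefore has a replicate check, and each interval covers counting error only, since PCR reads without molecular identifiers are not independent molecules. Reads assigned to genes came to 22082565 in AF357425-High whole-cell RNA and 21693030 in AF357425-Low whole-cell RNA. The pulldown libraries held 25857770 such reads in AF357425-High and 27832061 in AF357425-Low.

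The kinds of RNA differed between whole-cell and pulldown libraries. Protein-coding genes took 91.6% and 91.0% of the reads in AF357425-High and AF357425-Low whole-cell RNA, against 28.9% and 33.0% in the pulldowns. The mitochondrial ribosomal RNAs mt-Rnr1 and mt-Rnr2 took 63.4% and 59.8% of the pulldown reads, against 0.0926% and 0.0583% in whole-cell RNA. The 20 most abundant genes held 72.6% of the AF357425-High pulldown and 68.2% of the AF357425-Low pulldown, against 16.8% and 18.5% of the whole-cell libraries. Genes annotated as snoRNAs took 0.0107% and 0.0128% of the pulldown reads.

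**Figure D1:**
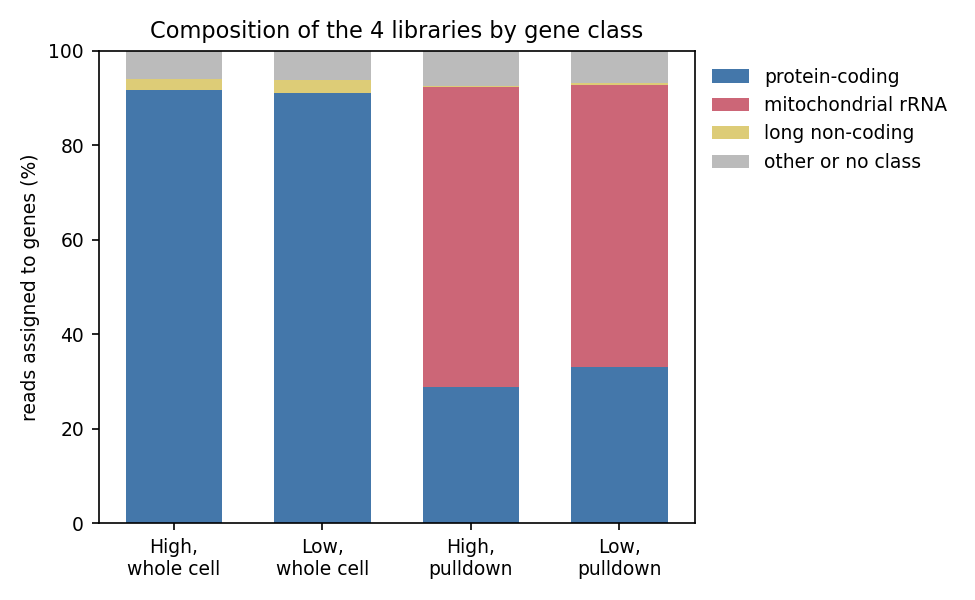
Percent of gene-assigned reads (y axis) by kind of RNA in each of the 4 libraries (x axis). Protein-coding reads make up 91.6% and 91.0% of the whole-cell libraries, and mitochondrial ribosomal RNA makes up 63.4% and 59.8% of the pulldowns.

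AF357425 itself (ENSMUSG00000088294; GRCm38 chromosome 12, 109636012 to 109636080, 69 nt, inside the span of the noncoding host gene Rian at 109603945 to 109661716) had 0 reads in all 4 libraries. These counts of 0 allow up to 0.136 and 0.138 counts per 1e6 gene-assigned reads (CPM) in AF357425-High and AF357425-Low whole-cell RNA, and up to 0.116 and 0.108 CPM in the pulldowns. The sample titles call the whole-cell libraries long RNA, and how well they keep an RNA of 69 nt is not known. The limits therefore bound its reads in these libraries and not its amount in the cells. With 0 reads, the states named by the labels could not be checked by the target in these libraries. In whole-cell RNA, AF357428 and AF357341 of the same cluster had 6 and 9 reads in AF357425-High and 5 and 9 reads in AF357425-Low. Rian, whose introns hold the snoRNA cluster, had a whole-cell log2 ratio of -0.14 (95% interval -0.19 to -0.10) for AF357425-High against AF357425-Low and a pulldown ratio of 0.18 (0.11 to 0.26). The maternally expressed long noncoding RNA Meg3 had ratios of -0.29 (-0.33 to -0.24) and -0.47 (-0.62 to -0.32). The paternally expressed Dlk1, a Notch-related ligand, had 0.20 (-0.19 to 0.58) and -0.49 (-1.13 to 0.12), and the deiodinase gene Dio3 had 0.13 (-0.14 to 0.40) and 0.49 (0.30 to 0.67). No member of the Dlk1-Dio3 list passed the 2-fold line, and the list's median was 0.03 over 9 members in whole-cell RNA and 0.18 over 5 members in the pulldown.

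AF357425-High against AF357425-Low in whole-cell RNA asks how the transcriptome differs between the states. Cartilage genes were higher in AF357425-High: Cnmd (ENSMUSG00000022025), which encodes the cartilage protein chondromodulin, by a log2 ratio of 2.73 (95% interval 1.92 to 3.65; 99 against 14 reads), and Col2a1, the main collagen of cartilage, by 1.24 (1.11 to 1.36; 1922 against 766 reads). Also higher were Igfbp2, a binding protein of insulin-like growth factors (1.24, 1.15 to 1.34), the granzyme gene Gzme (1.45, 1.19 to 1.72) and the mast cell protease gene Mcpt8 (1.34, 1.17 to 1.51). Lower were the secreted angiopoietin-like protein gene Angptl7 (-1.89, -2.08 to -1.70), the peptide hormone gene Cck (-1.37, -1.73 to -1.02) and the monocyte-attracting chemokines Ccl7 (-1.51, -1.80 to -1.23) and Ccl2 (-1.24, -1.46 to -1.03). Cck fell short of the line with library totals, median-of-ratios scaling and totals without the 20 most abundant genes (-1.31, -1.35 and -1.34), and Ccl2 with the totals of either kind (-1.18 and -1.21). The H/ACA box snoRNA Snora73b was lower as well (-1.89, -2.54 to -1.28; 29 against 101 reads). In all, 15 of 13519 genes were higher and 18 lower by more than 2-fold with their whole interval, and 92.8% of genes lay within 1.5-fold. Of these, 6 higher and 7 lower genes were protein coding, and 4 higher and 8 lower genes were pseudogenes. The pseudogenes, among them Vcp-rs (-2.50, -2.74 to -2.26), are uncertain because they share sequence with other genes. Col2a1, Mcpt8, Angptl7, Cck and Snora73b overlap another annotated gene, so their reads are uncertain too.

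Cell-cycle genes lay below 0 as a group in whole-cell RNA. All 42 measured genes of the proliferation list were negative, with a median of -0.27, below all 10000 random lists of genes of like expression (percentile 0.00), although none passed the line. Cenpe, a kinesin of the mitotic spindle, had -0.90 (-1.07 to -0.73), the topoisomerase Top2a -0.75 (-0.84 to -0.66), the spindle checkpoint kinase Bub1b -0.73 (-0.96 to -0.50) and the proliferation marker Mki67 -0.45 (-0.52 to -0.37). Of 54 replication-dependent histones, 46 were negative and none passed the line, with a median of -0.36 at percentile 0.00; Hist1h1c had -0.60 (-0.66 to -0.53). The chondrocyte markers stood at the other end, with a median of 0.84 above all random lists, all 5 positive and 2 past the line, and the aggrecan gene Acan at 0.84 (0.07 to 1.66). Interferon-response genes had a median of 0.22 (percentile 99.9), 17 of 22 positive and none past the line, with the RNA helicase gene Dhx58 at 0.95 (0.51 to 1.41) and Ifit1 at 0.79 (0.42 to 1.17). Cholesterol synthesis genes had a median of 0.19 (percentile 99.99), with 16 of 21 positive.

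Matrix genes went in both directions in whole-cell RNA. The matrix protease and inhibitor list had a median of -0.16 (percentile 0.06), with 25 of 33 negative, and the other extracellular matrix list had -0.13 (percentile 0.09), with 24 of 40 negative; neither held a gene past the line. Fibronectin (Fn1) had -0.42 (-0.43 to -0.42), decorin (Dcn) -0.62 (-0.80 to -0.45), the stromelysin gene Mmp3 -0.98 (-1.21 to -0.75) and fibromodulin (Fmod) 0.85 (0.76 to 0.94). The 30 collagens had a median of 0.01 (percentile 77.5), with Col3a1 at -0.45 (-0.48 to -0.42). The 18 integrin subunits, the receptors that bind cells to matrix, had a median of -0.07 (percentile 20.6), none past the line, with Itga1 at 0.48 (0.40 to 0.56) and Itga7 at -0.62 (-0.81 to -0.43). The 70 integrin signalling genes had a median of -0.01 (percentile 54.8), with the focal adhesion kinase relative Ptk2b at -0.74 (-0.89 to -0.60) and the integrin activator Fermt2 at 0.38 (0.32 to 0.44).

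Of the lists of RNA processing in whole-cell RNA, only the H/ACA box snoRNAs held a gene past the line. The snoRNA host genes, whose introns carry snoRNAs, had a median of 0.10 (percentile 99.4; 18 of 27 positive), with Snhg1 at 0.50 (0.33 to 0.66). The C/D box snoRNAs had 0.34 over 4 members (percentile 89.9), the H/ACA box snoRNAs -0.01 over 5 and the Cajal body RNAs 0.13 over 2. The C/D snoRNP proteins, which bind the snoRNAs, had 0.02 (percentile 63.8), with fibrillarin (Fbl) at 0.18 (0.05 to 0.32), and the H/ACA snoRNP proteins had 0.13. The splicing factors had 0.04 (percentile 97.0), ribosome biogenesis genes 0.02 and cytoplasmic ribosomal proteins 0.03 (percentile 98.2; 97.0 at a mean of at least 5 CPM, inside the central 95%). The small nuclear and other structured RNAs had -0.36 over 4 members (percentile 0.62), with the nuclear long noncoding RNA Malat1 at -0.58 (-0.58 to -0.57). With library totals in place of the trimmed mean of M values (TMM) the split was 18 higher and 14 lower, against 15 and 18.

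AF357425-High against AF357425-Low in the fibrillarin pulldown asks which RNAs recovered with fibrillarin differ between the states. Antiviral interferon-response genes were higher in AF357425-High, with 28 of 30 measured members past the 2-fold line and a median log2 ratio of 3.02, while 95% of random lists lay between -0.19 and 0.23. The chemokine Cxcl10 was higher by 4.45 (95% interval 4.27 to 4.64; 4301 against 259 reads), the mitochondrial nucleotide kinase Cmpk2 by 4.44 (4.05 to 4.87), the guanylate-binding protein gene Gbp2 by 4.02 (3.86 to 4.18) and Ifit3 by 3.76 (3.66 to 3.87; 7866 against 765 reads). The DNA-sensing Ifi200 family member Ifi206 (ENSMUSG00000037849) had the largest ratio, 6.27 (5.22 to 7.60; 410 against 7 reads), and Ifi207 (4.04, 3.71 to 4.39), Ifi209 (5.24, 4.09 to 6.71), the nuclear body protein gene Sp110 (4.98, 4.24 to 5.83) and the GTPase gene Tgtp2 (4.48, 3.94 to 5.07) were higher too. The Ifi200 and Tgtp genes have close paralogs, and Mx1 (4.51, 4.03 to 5.02) is annotated as a pseudogene in the reference assembly, so the values of these genes are uncertain, as are those of Cxcl10, Gbp2 and Sp110, which overlap another annotated gene. The members that did not pass, chosen here after their values were seen, were Irf9 (0.34, 0.15 to 0.53) and Irf1 (0.08, -0.22 to 0.39). Outside the interferon list, the thromboxane receptor gene Tbxa2r was higher by 5.56 (3.97 to 7.86; 107 against 3 reads) and the endosomal sensor of double-stranded RNA Tlr3 by 2.6 (2.42 to 2.78).

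**Figure D2:**
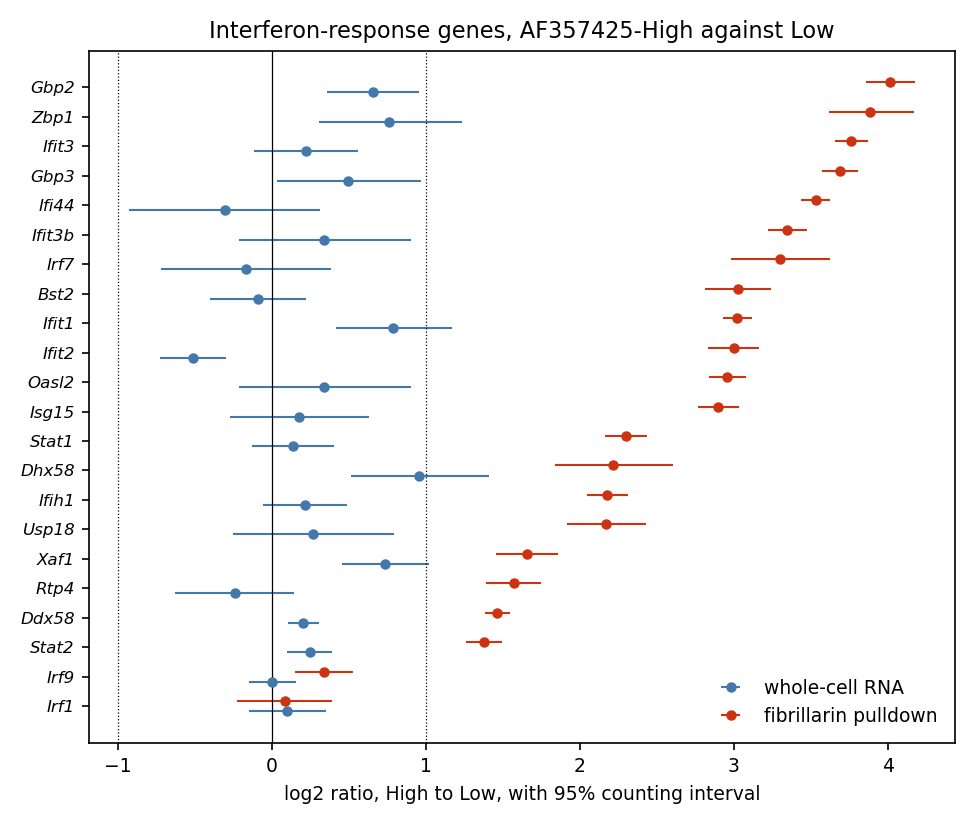
Log2 ratio of AF357425-High to AF357425-Low (x axis) for each of the 22 interferon-response genes measured in both kinds of library (y axis), with bars for the 95% counting interval and dotted lines at 2-fold. Ratios in the pulldown reach 4.02 for Gbp2, which has 0.65 in whole-cell RNA.

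In the AF357425-High pulldown, 3 of 4 measured genes of the C/D box snoRNA list and 4 of 23 host genes were lower. The snoRNAs were Snord83b (-4.83, -6.30 to -3.69; 6 against 226 reads), Snord92 (-4.49, -6.13 to -3.23; 5 against 148 reads) and Snord118, the U8 RNA needed for ribosomal RNA maturation (-2.24, -2.61 to -1.89; 76 against 475 reads). Snord17 had 0.32 (0.11 to 0.54), and the median of the group was -3.36 (percentile 0.00). Summed over the 113 genes of the C/D box list, which were picked by name, the pulldown held 22.9 CPM (exact 95% interval 21.1 to 24.8) in AF357425-High. In AF357425-Low it held 49.9 CPM (47.3 to 52.6), and the whole-cell libraries held 21.1 and 16.5 CPM. By library totals, these 3 genes made the difference of the sums: the other 110 held 19.5 CPM (17.9 to 21.3) in AF357425-High and 19.4 CPM (17.8 to 21.1) in AF357425-Low, a split made after the values were seen. The ratios of single genes are after TMM scaling, and library totals move the median of all genes by -0.29 against it. The near-equal sums of the 110 therefore hold for library totals only. Snord17 alone gave 345 of their 505 reads in the AF357425-High pulldown. The 13 measured genes annotated as snoRNAs of any family had a median of -0.17 (percentile 25.2). All 1063 genes so annotated took 0.0107% of the reads in the AF357425-High pulldown and 0.0128% in the AF357425-Low pulldown. The host genes Snhg15 (-2.92, -3.39 to -2.49; 47 against 471 reads), Snhg17 (-2.25, -2.66 to -1.86), Rack1 (-1.84, -2.19 to -1.50) and Snhg1 (-1.43, -1.68 to -1.19) were lower, and the 23 host genes had a median of -0.31 (percentile 0.27). Cajal body RNAs went the other way, all 5 positive with a median of 1.07 (percentile 99.9), and Scarna6 (2.69, 1.92 to 3.53) and Scarna2 (1.3, 1.14 to 1.47) were higher, the latter not past the line with library totals. Among C/D snoRNP proteins (median 0.47, percentile 98.0, or 97.3 at a mean of at least 5 CPM; 6 of 9 positive), the assembly factor Znhit6 was higher by 2.08 (1.86 to 2.30), and the messenger RNA of fibrillarin had 1.20 (0.93 to 1.46). Snord83b, Snord92, Snord17, Scarna6, Snhg15, Snhg17, Snhg1 and Rack1 overlap another annotated gene, and reads of a host and its snoRNA cannot be separated here.

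Of 42 proliferation genes, 7 were lower in the AF357425-High pulldown and none higher, 39 were negative, and the median was -0.43 (percentile 0.00). Among them were the kinesins Kif23 (-1.67, -1.92 to -1.42) and Cenpe (-1.25, -1.35 to -1.16) and the mitotic kinases Plk1 (-1.55, -1.97 to -1.15) and Bub1 (-1.53, -1.82 to -1.25). The replication-dependent histones had a median of -0.63 (percentile 0.20), 12 of 15 negative and none past the line, but -0.037 (percentile 47.4) among those with a mean of at least 5 CPM. Of 20 chemokines and cytokines (median 0.38, percentile 99.4, but 0.24 and 92.5 at a mean of at least 5 CPM), 5 were higher and 3 lower, with the alarmin Il33 at 2.21 (1.54 to 2.93), the neutrophil-attracting Cxcl2 at -2.51 (-3.34 to -1.78) and the NF-kappa-B inhibitor Nfkbia at -1.79 (-2.08 to -1.50). This list shares Cxcl10, its highest member at 4.45, with the interferon list. The integrin subunits had a median of -0.32 over 15 members (percentile 2.04) and of -0.14 (percentile 10.5) at a mean of at least 5 CPM; the collagen receptor Itga10 was lower (-2.08, -3.22 to -1.10), and Itgb3 had 0.79 (0.54 to 1.04). The 68 integrin signalling genes had a median of 0.03 (percentile 57.1), none past the line, with Rhob at -1.07 (-1.37 to -0.78). Among collagens (median -0.11, percentile 10.5), Col27a1 (-1.86, -2.29 to -1.45) and Col15a1 (-1.28, -1.53 to -1.03) were lower. Among other extracellular matrix genes (median 0.17, percentile 96.4), thrombospondin Thbs1 was higher (1.24, 1.22 to 1.26), but had 0.94 with library totals and did not pass the line there. The 73 cytoplasmic ribosomal proteins had a median of 0.44, above all random lists, with 66 positive and none past the line. Il33, Col15a1 and Col27a1 overlap another annotated gene.

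Further genes past the line in the pulldown did not belong to the lists. Lower in AF357425-High were the microRNA gene Mir6240 (-4.84, -5.36 to -4.37; 37 against 1402 reads), the potassium channel partner Kcnip3 (-4.27, -6.17 to -2.87), the kinase gene Nek3 (-3.82, -5.30 to -2.65), the mitochondrial malic enzyme Me3 (-3.61, -4.96 to -2.52), the phosphoinositide kinase subunit Pik3r5 (-2.85, -3.69 to -2.10) and Plcl1 (-2.72, -3.03 to -2.42). Kcnip3, Me3 and Plcl1 overlap another annotated gene and are uncertain. In all, 368 of 10736 genes were higher and 311 lower, and 67.1% lay within 1.5-fold. With library totals in place of TMM the median of all genes moved by -0.29, and the split became 238 higher and 608 lower.

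The differences between the states were compared across the 2 kinds of library over 10366 genes measured in both. Across genes, which are not independent replicates, the Pearson correlation of the log2 ratios was 0.107 and the Spearman correlation 0.088, and 52.6% had the same sign. The ratios had an SD of 0.278 across genes in whole-cell RNA and 0.746 in the pulldown. Of 9 genes higher in whole-cell RNA and 290 higher in the pulldown, 2 were shared, against 0.25 for independent sets: Mcpt8 (1.34 and 2.4) and the unnamed gene Gm44829 (1.76 and 3.10), named here after its values were seen. Of 12 and 273 lower genes, none was shared, against 0.32, and no gene passed the line in opposite directions.

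**Figure D3:**
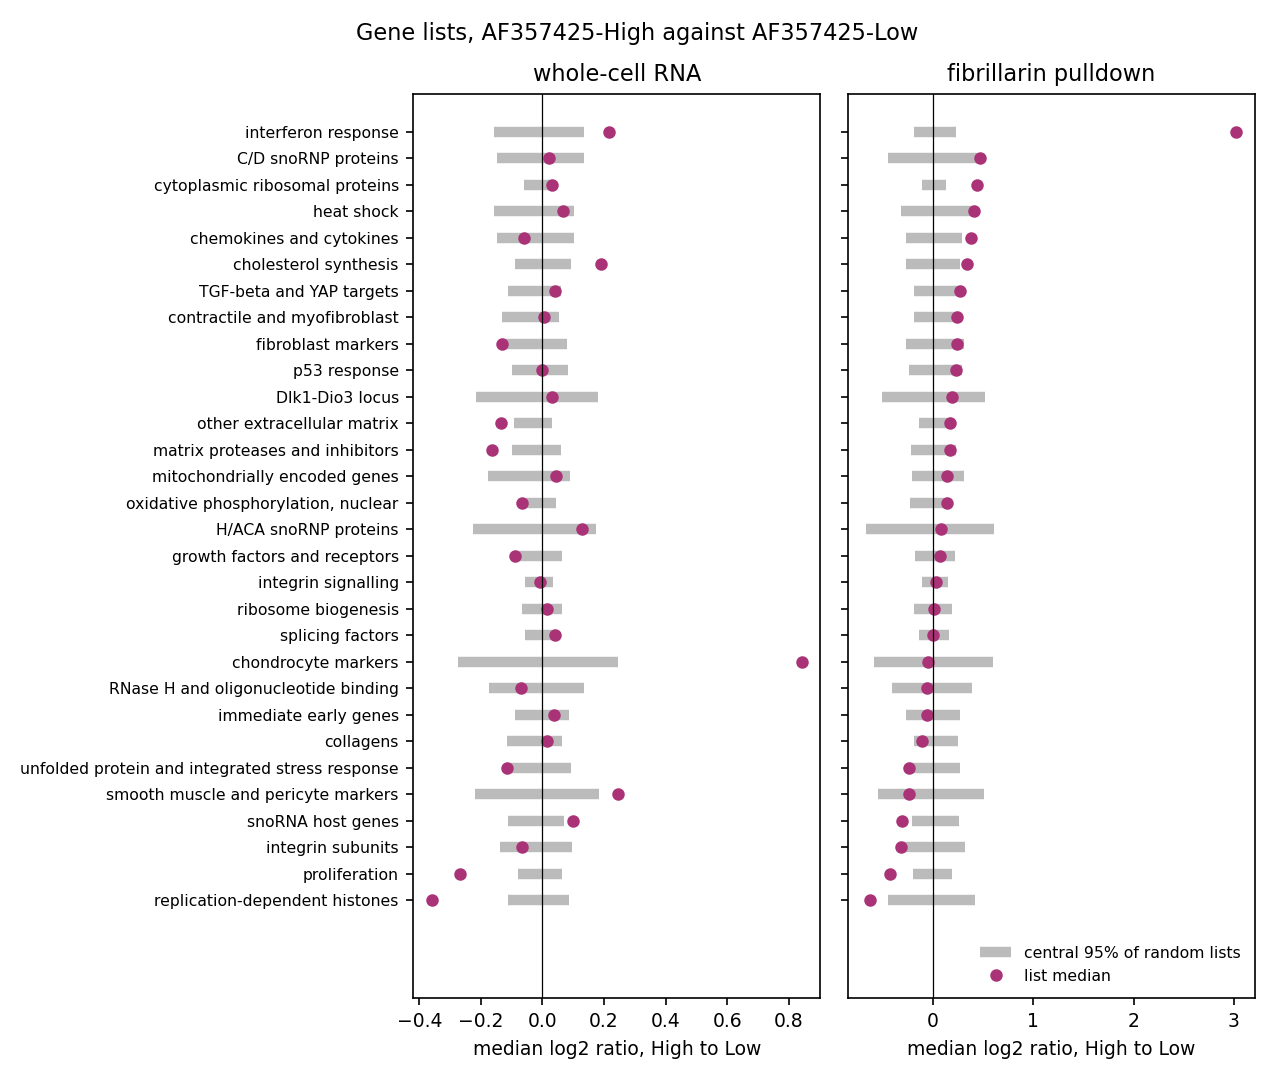
Median log2 ratio of AF357425-High to AF357425-Low (x axis) for the 30 gene lists plotted (y axis), in whole-cell RNA and in the pulldown, with grey bars for the central 95% of random lists and a different x scale in each panel. The interferon response stands at 3.02 in the pulldown and 0.22 in whole-cell RNA, and the proliferation list is negative in both, at -0.43 and -0.27.

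The pulldown against whole-cell RNA of the same state asks which RNAs were recovered with fibrillarin. The largest log2 ratio belonged to mt-Rnr1, the small mitochondrial ribosomal RNA, with 12.94 (95% interval 12.87 to 13.02) in AF357425-High and 13.14 (13.06 to 13.23) in AF357425-Low, and mt-Rnr2, the large one, had 7.06 (7.04 to 7.08) and 7.87 (7.84 to 7.89). Next to mt-Rnr1 came CT010467.1, a gene without a class in the annotation and named here after its values were seen. Its ratios were 11.72 (11.56 to 11.88) and 11.72 (11.55 to 11.89). It held 46985 and 42485 CPM of the pulldowns, against 13.9 and 12.6 CPM in whole-cell RNA. Gm26917 and Gm42418, chosen after their values were seen, went the other way. Gm26917 held 9.47 and 19.0 CPM of the pulldowns, against 32635 and 32963 CPM in whole-cell RNA. Gm42418 had 0 pulldown reads in both states, against 8860 and 8596 CPM in whole-cell RNA. The cause of these opposite differences was not tested, so they are not read as recovery with fibrillarin. The cytochrome oxidase gene mt-Co2 was higher by 5.33 (4.89 to 5.81) and 5.38 (4.84 to 5.97), and mt-Atp8, with 0 whole-cell reads, by at least 54.1-fold and 40.8-fold. Of the small RNAs, Scarna9 (6.78, 5.22 to 9.06, and 5.56, 4.18 to 7.45), Scarna17 (5.67, 3.78 to 8.73, and 5.08, 3.19 to 8.15), Snord118 (2.70, 1.74 to 3.82, and 5.53, 4.54 to 6.75) and Snord17 (2.09, 1.72 to 2.49, and 2.29, 1.89 to 2.72) were higher in both states. Also higher in both were Cxcl10 (8.84, 7.86 to 10.06, and 6.66, 4.79 to 9.71), the heparin-binding growth factor Ptn (4.76, 4.53 to 5.01, and 6.63, 6.24 to 7.04), Mfsd4a (6.30, 5.17 to 7.75, and 7.12, 5.76 to 9.0) and the monoamine transporter gene Slc18a2, with 0 whole-cell reads and at least 52.1-fold and 96.1-fold more in the pulldown. Scarna9, Scarna17, Snord17, Cxcl10 and Mfsd4a overlap another annotated gene and are uncertain. For mt-Co2 and mt-Atp8 an overlap could not be read from the RefSeq spans, so their ratios are uncertain too.

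Several abundant messenger RNAs were lower in the pulldown, some of them with few or no reads there. Integrin-linked kinase (Ilk, ENSMUSG00000030890), which couples integrins to the cytoskeleton, had 4325 whole-cell and 2 pulldown reads in AF357425-High, a log2 ratio of -11.31 (-14.35 to -9.45), and 3924 and 0 reads in AF357425-Low, at least 1678-fold fewer. The G protein subunit gene Gnas had -9.57 (-10.20 to -9.01) and -9.18 (-9.66 to -8.73), the nuclear receptor gene Nr2f6 -10.16 (-15.47 to -7.68) and -7.18 (-8.39 to -6.19), metallothionein Mt2 -9.40 (-14.71 to -6.92) and -8.37 (-11.42 to -6.51) and the smooth muscle protein transgelin (Tagln) -6.46 (-6.69 to -6.25) and -6.68 (-6.92 to -6.44). The Mediator subunit Med10 had 0 pulldown reads and was lower by at least 247-fold and 251-fold, and the mitochondrial RNA-binding protein gene Slirp by at least 173-fold and 155-fold. Of these, Ilk, Gnas, Slirp and Tagln overlap another annotated gene and are uncertain.

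Lists in this comparison are given relative to the median of all genes, which was -2.15 in AF357425-High and -1.75 in AF357425-Low. Mitochondrially encoded genes stood at 6.51 and 5.91 and interferon-response genes at 5.54 and 2.91, all above every random list. Summed, the 13 mitochondrial messenger RNAs took 1.90% and 1.98% of the pulldown reads, against 0.962% and 0.986% in whole-cell RNA. Of the interferon-response genes, 24 of 30 and 11 of 26 were past the line. Ifi44 had 7.43 (7.0 to 7.90) and 3.95 (3.54 to 4.39) before the median was subtracted. Cajal body RNAs stood at 4.84 and 3.85, C/D box snoRNAs at 2.73 and 5.21, chemokines and cytokines at 2.05 and 1.45, growth factors and receptors at 1.01 and 0.81 and proliferation genes at 0.97 and 0.77, all above the central 95% of random lists. The chemokine and cytokine list shares Cxcl10 with the interferon list. The Cajal body values are medians over 5 and 4 members, and the C/D box values over 4 and 5. Before the median was subtracted, 2 of the 4 C/D box members in AF357425-High and 4 of the 5 in AF357425-Low were positive. Summed over the C/D box list, the AF357425-High pulldown held 22.9 CPM, against 21.1 CPM in whole-cell RNA. The AF357425-Low pulldown held 49.9 CPM, against 16.5 CPM. Summed over the 9 genes of the Cajal body list, the pulldowns held 60.3 and 31.5 CPM, against 121 and 123 CPM in whole-cell RNA. Scarna2 made up most of the whole-cell sum and was lower in the pulldown (-1.77, -1.88 to -1.66, and -2.81, -2.95 to -2.67). The 46 genes classed here with Cajal body RNAs, a class that takes in all genes typed as guide RNA in RefSeq, went the other way. They took 0.101% and 0.0654% of the pulldown reads, against 0.0149% and 0.0148% in whole-cell RNA. At a mean of at least 5 CPM the growth factors and receptors stood at 0.76 in AF357425-Low, inside the central 95% (percentile 96.7). Replication-dependent histones stood at -2.38 and -1.84 (both percentile 0.00), cytoplasmic ribosomal proteins at -0.47 and -0.98 and nuclear genes of oxidative phosphorylation at -0.76 and -1.02, below the central 95% of random lists. Integrin signalling genes stood at -0.10 (percentile 1.77) and -0.25 (percentile 1.35), and the integrin subunits at 0.50 (percentile 84.1) and 0.57 (percentile 87.4), with the laminin receptor Itga3 lower in both states (-4.51, -4.72 to -4.30, and -4.39, -4.58 to -4.20). The H/ACA box snoRNAs had -1.71 over 2 genes in AF357425-High (percentile 66.3) and -5.03 over 3 genes in AF357425-Low (percentile 1.81) before the median was subtracted. Scaled by library totals, 308 of 12773 genes were higher and 9459 lower in AF357425-High, 330 of 12774 higher and 7965 lower in AF357425-Low, and 176 higher and 7502 lower in both. TMM moved the median of all genes by 1.84 and 1.43 and gave 1682 higher and 2884 lower genes in AF357425-High and 1731 and 3365 in AF357425-Low. The pulldown was depleted of ribosomal RNA and prepared as another kind of library than whole-cell RNA. No library of an unspecific pulldown was used here, so these ratios hold the differences in preparation too. The sample titles call the whole-cell libraries long RNA, and how well they keep small RNAs is not known. Ratios of snoRNAs and Cajal body RNAs are therefore uncertain. The strand setting of the counting is not given in the sources used here and could differ between the kinds of library, which would change the ratios of overlapping genes.

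The change of the pulldown-to-whole-cell ratio between the states sets each gene's pulldown difference against its whole-cell difference. The ratio of interferon-response genes was higher in AF357425-High, with 17 of 22 past the line and a median log2 change of 2.43, above all random lists. Ifi44 was higher by 3.84 (95% interval 3.24 to 4.44), Ifit3 by 3.54 (3.20 to 3.89), Ifit2 by 3.51 (3.24 to 3.78), the transcription factor Irf7 by 3.46 (2.85 to 4.08) and the immune checkpoint ligand Cd274 by 3.52 (2.90 to 4.15). Lower were the host genes Snhg15 (-3.20, -3.72 to -2.68), Snhg17 (-2.22, -2.64 to -1.79), Snhg1 (-1.92, -2.21 to -1.63) and Rack1 (-1.89, -2.24 to -1.55), and the list of 22 had a median of -0.42 (percentile 0.00). The cartilage genes Cnmd (-2.78, -3.61 to -1.95) and Col2a1 (-1.22, -1.44 to -1.01) were lower as well, and the chondrocyte markers had a median of -0.97 over 4 members (percentile 0.09). Cnmd and Col2a1 were higher in whole-cell RNA, and that difference enters the change with its sign turned. The chondrocyte list had a median of 0.84 in whole-cell RNA and -0.05 in the pulldown. Its change therefore comes mainly from the whole-cell pair and is no separate result. The adhesion molecule Icam1 (-2.55, -3.34 to -1.75) and the stress gene Gadd45b (-2.27, -2.65 to -1.90) were also lower. Of these, Cd274, Col2a1 and the 4 host genes overlap another annotated gene.

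Among chemokines and cytokines (median 0.39, percentile 98.1, but 0.12 and 66.9 at a mean of at least 5 CPM), Ccl7 (2.19, 1.90 to 2.48) and Ccl2 (1.49, 1.25 to 1.72) were higher, and Malat1 was higher by 2.35 (2.32 to 2.38) among the small nuclear and other structured RNAs (median 0.77, percentile 98.0). Ccl7 and Ccl2 were lower in whole-cell RNA, and that difference enters the change with its sign turned. Malat1 overlaps another annotated gene. Znhit6 was higher by 2.17 (1.88 to 2.45), with fibrillarin at 1.01 (0.72 to 1.3). Cytoplasmic ribosomal proteins had a median of 0.41, above all random lists. Nuclear genes of oxidative phosphorylation had 0.25 (percentile 99.97) and other extracellular matrix genes 0.29 (percentile 98.4), and with library totals these medians were -0.11 and -0.073; at a mean of at least 5 CPM the former was 0.20, inside the central 95% (percentile 97.2). The integrin subunits had -0.22 (percentile 5.6), the integrin signalling genes 0.07 (percentile 60.9) and the proliferation genes -0.19 (percentile 6.02), none with a gene past the line. In all, 280 of 10300 genes were higher and 186 lower, and with library totals the median of all genes moved by -0.36 and the split became 124 and 565.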

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

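Of the tests in this part, the test of separate cultures behind the kinds of library was chosen after the result was seen.

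The snoRNA host genes differed in direction between the kinds of library, with a median log2 ratio of AF357425-High to AF357425-Low of 0.10 in whole-cell RNA and -0.31 in the pulldown. Gene by gene, the change of their pulldown-to-whole-cell ratio had a median of -0.42, below all random lists, with 16 of 22 negative. This change is computed from the same libraries, so it restates the difference for each gene and is no separate check. A difference between replicate libraries was not tested, as each group has 1. Fragments that overlapped several genes, which enter no gene's count, were 1.05% and 1.09% of the AF357425-High and AF357425-Low whole-cell fragments and 9.38% and 8.54% of the pulldown fragments. Fragments that overlapped no counted feature were 25.7% and 24.9% of the whole-cell fragments and 8.90% and 6.57% of the pulldown fragments. The annotation and the strand setting are not given in the sources used here, so fragments from within genes could be among them. These shares were flagged because they hold signal outside the gene counts.

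Interferon-response genes were higher in the AF357425-High pulldown, with a median log2 ratio of 3.02, while the median in whole-cell RNA was 0.22. Library scaling is argued against, since the lowest median over 5 scalings was 2.73. Reads of overlapping genes are argued against too, since the 18 members without an overlapping gene had a median of 3.42, against 2.6 for the 12 with one. Separate cultures behind the pulldown and whole-cell libraries cannot be told apart from recovery with fibrillarin: the list also stood 2.91 above all genes in the AF357425-Low pulldown against whole-cell RNA (95% of random lists between -0.88 and 0.63), and the 4 libraries include no whole-cell library known to come from the pulldown cultures. The AF357425 state and an innate response to the transfected nucleic acid stay open and untested.

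Some abundant messenger RNAs, Ilk and Med10 among them, were lower in both pulldowns than in whole-cell RNA by far more than the median of all genes (-2.15 and -1.75): 161 protein-coding genes with at least 10 CPM in whole-cell RNA had a mean log2 ratio of -5 or less. Of these, 60.9% (98 genes) overlap another annotated gene, above random lists of like expression (95% between 39.8% and 54.7%), which is consistent with reads lost as ambiguous where genes overlap, the class that took 9.38% of the AF357425-High pulldown fragments. The share did not rise with depletion outside these genes, with 44.7% at mean ratios from -5 to -3 and 48.7% from -3 to -1, and the other 63 have no overlap among the RefSeq spans used here, while the annotation behind the counts is not given in the sources used here. The median genomic span of all 161 genes was 10.5 kb, below random lists (95% between 19.4 and 30.1 kb), and among 4428 protein-coding genes without an overlap the pulldown-to-whole-cell ratio rose with span (Spearman correlation across genes 0.33). A larger share of unspliced RNA in the pulldown stays open, since intron reads cannot be told from exon reads in these counts.

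Proliferation genes were negative in AF357425-High in both kinds of library. Library scaling is argued against as the cause, since the highest of the medians over 5 scalings in each kind of library was -0.20. A trend with expression level and genomic span is argued against as well, since the whole-cell median was -0.28 after both trends were removed, with 95% of random lists between -0.07 and 0.07. A difference in cell-cycle stage after the release from KN93, in cell density or in the AF357425 state stays open, as each state has 1 library of each kind.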

How the results depend on the processing

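The alternative of protein-coding genes without an overlapping gene was chosen after the data were seen. Of the list medians under the alternatives, 496 kept their side of the random-list limits, 15 moved outside the limits, 8 moved inside and 3 reversed. For this tally the main percentiles were redrawn with 2000 random lists. The heat shock genes in the pulldown count among the 15, with percentiles of 98.1, 99.4 and 98.1 under the alternatives. Over 10000 random lists their main percentile of 97.6 already lay outside the limits, so they did not truly move. A sign change was counted as a reversal only for lists outside the limits in the main result. Thus the small nuclear and other structured RNAs count among those that moved outside. In AF357425-High they went from 0.68 to -1.72 at a mean of at least 5 CPM, pulldown against whole-cell RNA, relative to all genes. The values of named genes kept their side of the line in 603 cases and fell short of it in 17, and none reversed. No paired analysis was possible because each group has 1 library, and no library could be left out. Counts are given as higher and lower genes. With library totals in place of TMM, the pulldown gave 238 and 608 and the change of the pulldown-to-whole-cell ratio 124 and 565. Among lists outside the random-list limits, library totals reversed the median of TGF-beta and YAP targets in the pulldown (-0.031). In the change of the ratio they reversed those of other extracellular matrix (-0.073) and nuclear oxidative phosphorylation genes (-0.11). A shift of all genes by -0.29 in the pulldown and -0.36 in the change of the ratio goes with this setting. Positive medians of other lists that were smaller than the shift turned negative too. For the pulldown against whole-cell RNA in AF357425-High, TMM gave 1682 and 2884, median-of-ratios 1810 and 2741, totals of protein-coding genes 1369 and 3382 and totals without the 20 most abundant genes 1291 and 3564. In AF357425-Low the same settings gave 1731 and 3365, 1844 and 3234, 1814 and 3265, and 1613 and 3509. All of these move the median of all genes by 1.36 to 1.90. The remaining counts are for another line or other genes tested, which sets them by construction, in the order whole-cell RNA, pulldown and change of the ratio. The 2-fold line without the interval gave 103 and 84, 731 and 806, and 675 and 713. The 1.5-fold line gave 59 and 77, 828 and 843, and 730 and 659. The 4-fold line gave 3 and 5, 113 and 40, and 46 and 9. No filter gave 35 and 29, 932 and 756, and 517 and 398. A mean of at least 5 CPM gave 7 and 8, 188 and 114, and 148 and 85. Protein-coding genes without an overlapping gene gave 4 and 4, 166 and 137, and 137 and 87. At least 50 reads per library gave 173 and 84 for the change of the ratio. For the pulldown against whole-cell RNA, AF357425-High before AF357425-Low, the 4-fold line gave 192 and 5732, and 162 and 4589, and genes without an overlap gave 100 and 4381, and 114 and 3666. In the same order, no filter gave 667 and 11443, and 693 and 9715, a mean of at least 5 CPM gave 168 and 7258, and 182 and 6146, and the 1.5-fold line gave 403 and 10576, and 504 and 9324. The Pearson correlation across genes between the kinds of library was 0.131 over protein-coding genes, against 0.107, and the integrin subunits in the pulldown had a median of -0.14 inside the random-list limits at a mean of at least 5 CPM; the cause was not tested. Over all expression levels together, a change of 2.5-fold simulated with counting error only was recovered for 55.6% to 71.1% of genes.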

Other observations

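Stress and signalling genes changed singly in the pulldown. Of the p53 response (median 0.23, percentile 94.5), the apoptosis genes Pmaip1 (log2 ratio 1.63, 95% interval 1.46 to 1.79) and Perp (1.43, 1.28 to 1.57) were higher in AF357425-High, while the list had -0.00 in whole-cell RNA. Of the unfolded protein and integrated stress response (-0.24, percentile 4.17), the pseudokinase gene Trib3 (-2.28, -3.06 to -1.58) and the lipoprotein receptor gene Vldlr (-1.30, -1.49 to -1.12) were lower, and the whole-cell median was -0.11 (percentile 1.87) with no gene past the line. The heat shock genes had 0.41 (percentile 97.6) and 0.07 in whole-cell RNA, and the immediate early genes -0.06 and 0.04, with the transcription factor Egr2 lower in the pulldown (-1.31, -1.62 to -1.02). Among growth factors and receptors (0.07 in the pulldown, -0.09 at percentile 2.95 in whole-cell RNA), the BMP antagonist Grem1 (1.25, 1.17 to 1.32) and Fgf18 (1.95, 1.08 to 2.91) were higher in the pulldown, while Grem1 had -0.71 (-0.74 to -0.67) in whole-cell RNA. TGF-beta and YAP targets had 0.26 (percentile 97.9) and 0.04, with the stretch-responsive Ankrd1 higher in the pulldown (1.40, 1.18 to 1.62). With library totals the pulldown median of these targets was -0.031, and Ankrd1, Grem1, Fgf18 and Perp no longer passed the line. Vldlr and Egr2 overlap another annotated gene.

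Cholesterol synthesis genes had 0.34 in the pulldown (percentile 99.2), with the phosphomevalonate kinase gene Pmvk higher (1.92, 1.20 to 2.69). Nuclear oxidative phosphorylation genes had 0.14 (percentile 97.1) and -0.07 in whole-cell RNA (percentile 0.86), with Ndufb4 (1.65, 1.08 to 2.25) and Uqcr11 (1.89, 1.04 to 2.82) higher in the pulldown, and mitochondrially encoded genes had 0.14 and 0.05. With library totals Pmvk, Ndufb4 and Uqcr11 did not pass the line, and neither did Uqcr11 with totals without the 20 most abundant genes. Among genes of RNase H and oligonucleotide binding (-0.06 and -0.07), the paraspeckle protein gene Pspc1 was lower in the pulldown (-1.30, -1.49 to -1.10). Splicing factors had a pulldown median of 0.00, with Tra2a higher (1.49, 1.38 to 1.61), and ribosome biogenesis genes had 0.01, with Heatr1 lower (-1.24, -1.43 to -1.05). Small nuclear and other structured RNAs had 0.38 in the pulldown, where Malat1 was higher (1.77, 1.74 to 1.81) and the U5 RNA gene Rnu5g lower (-1.50, -1.78 to -1.23). The 11 measured genes annotated as small nuclear RNAs had -0.85 there (percentile 0.815), with 3 lower and none higher. Heatr1, Malat1 and Rnu5g overlap another annotated gene. The matrix proteases and inhibitors had 0.16 in the pulldown and the H/ACA snoRNP proteins 0.08. The only measured H/ACA box snoRNA there, Snora23, had 0.82 (0.35 to 1.29).

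Markers of cell types described the cultures. In whole-cell RNA the contractile and myofibroblast genes had a median of 0.01 (percentile 74.7), with smooth muscle actin (Acta2) at -0.20 (-0.22 to -0.18), and the fibroblast markers had -0.13 (percentile 3.26), with the progenitor marker Cd34 at -0.70 (-0.89 to -0.51). Smooth muscle and pericyte markers had 0.24 (percentile 99.3; 6 of 7 positive, none past the line), with Mcam at 0.46 (0.29 to 0.63). Skeletal muscle markers had 0.54 over 3 genes, adipocyte markers 0.15, endothelial markers -0.13, keratinocyte markers -0.18, macrophage and leukocyte markers -0.02 and Schwann and melanocyte markers -0.01, none with a gene past the line. In the pulldown the contractile list had 0.24, the fibroblast markers 0.24, smooth muscle -0.24, chondrocyte -0.05, adipocyte -0.43, endothelial -0.65 and Schwann and melanocyte markers 0.16. The keratinocyte list had 0.42 over 2 genes, of which Perp is named with the p53 response, and no macrophage or skeletal muscle marker was measured there.

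Of the 33 genes past the line between the states in whole-cell RNA, 12 were annotated as pseudogenes, and the largest ratio belonged to AC133509.1, a gene without a class in the annotation and named here after its values were seen, with 49 reads in AF357425-High and 1173 in AF357425-Low (-4.67, -5.12 to -4.26). Whether the states came from the same mice is not given in the sources used here, so a difference between mice cannot be told from a difference between states.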
